A study of Sus scrofa with 9 samples.

How the data were processed

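Total RNA of pig testis cells was sequenced in paired reads on the Illumina HiSeq 4000 from a directional library kit, per the labels' protocols. The genome build Sscrofa11.1 and the tool bcl2fastq are named in the submitters' processing notes. The aligner, the quantifier and the annotation are not given in the sources used here. Whether the strand was used in counting is not stated either, so overlapping and antisense genes are uncertain, as are members of gene families that share reads, such as ribosomal proteins.

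The authors deposited 2 tables with 1 column per library, of estimated counts per gene and of TPM. In the deposited values each estimated count equals the TPM of the same gene and library times a factor of the gene and a factor of the library, with a largest log deviation of 3.64e-14 over 16193 genes. The deposited TPM columns sum to less than the full scale of the unit, with 3.19 to 11.8% left out. The labels' 9 samples were matched to columns by the headings. Round spermatid columns carry the sample titles. Spermatocyte columns are headed with the name of the pachytene stage and spermatogonia columns with that of the KIT receptor, each with the same numbers as the titles; this match rests on the meaning of those names and is not stated by the labels, and another column with a number shared by a spermatogonia title was left unused. The other 6 library columns of the 15 were not used in any step. The labels speak of biological samples without naming animals, so p-values measure the spread between these libraries, which may be technical in part. Library totals were 64508555, 64639201 and 63528653 counts for spermatogonia 1, 2 and 3, 61887148, 59188641 and 61300897 for spermatocytes 2, 3 and 4, and 55812018, 47963279 and 56184816 for round spermatids 1, 2 and 3. The shallowest library, round spermatids 2, gives the least precise values, and counting error weighs most on genes under 1 CPM.

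Gene symbols were found for 14749 of the 22342 gene identifiers, and chromosomes for 13540 by matching the symbol to a RefSeq table of Sscrofa11.1. Markers PIWIL1, HSPA2, CREM and PGK2 had no matching symbol and are not analysed here. A symbol carried by several identifiers was taken from the one with the highest mean count.

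Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, libraries scaled with TMM factors, and all 9 libraries fitted together with edgeR 4.0.16 (glmQLFit, glmQLFTest) in R 4.3.3, with a common dispersion of 0.0316. The standard error of a log2 fold change was taken as its size divided by the square root of F. Adjusted p-values are Benjamini-Hochberg, called below 0.05. The 26 gene lists were fixed before the data were examined and tested against other genes with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, adjusted over the 26 lists, again with an estimated correlation, and with fry. They cover undifferentiated and differentiating spermatogonia, DNA replication, meiotic recombination, meiotic division, the piRNA pathway, spermatid transcription regulators, histone replacement, acrosome, axoneme, sperm ion channels, germline glycolysis, oxidative phosphorylation, ribosomal proteins, cohesin with condensin and CTCF, nuclear lamina, DNA and histone methylation, X-linked parents of retrogenes, autosomal retrogenes, Sertoli, Leydig, myoid, endothelial, leukocyte and erythrocyte markers, and immediate early genes. List members without a matching symbol dropped out. Found were 42 of 71 ribosomal protein genes, 4 of 11 autosomal retrogenes, 7 of 13 X-linked parents, 5 of 8 erythrocyte markers and a larger part of every other list. List counts below are of found members that passed the filter. X-linked genes were tested with camera among genes with a chromosome. Shares of counts were compared with exact permutation tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, permutations and plots.

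Named genes followed a rule fixed before the data were examined. It took, per comparison, the 5 largest rises and the 5 largest falls among called genes with a symbol, at least 50 CPM in the higher stage and no overlap of replicates. It also took up to 3 members per list in the majority direction and up to 2 in the other, a fixed set of stage markers, and the 5 most abundant genes enriched in each stage.

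The procedure was tested on simulated data, with counts drawn for the real genes and 200 genes changed. For spermatocytes against spermatogonia edgeR recovered 71% of 2-fold and 100% of 4-fold changes with 8 false calls over 16563 genes, for round spermatids against spermatocytes 71% and 98% with 11 over 16584, and for round spermatids against spermatogonia 78% and 97% with 15 over 16575. False calls were 4.47, 6.11 and 7.89% of calls, and with DESeq2 20.7, 17.3 and 21.0%. A planted list was found in each comparison, and 0 of 25 random lists were called. Genes were drawn independently, most were unchanged, and the spread was edgeR's own estimate per gene, the same in all stages. The simulation therefore does not test lists of correlated genes or comparisons where most genes differ, and cannot rank edgeR against DESeq2. With the real libraries regrouped across stages, up to 8, 15 and 16 lists were called in the 3 comparisons.

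Alternatives chosen before the data were examined were RLE size factors, upper-quartile factors or none, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), a TREAT test against a log2 change of 1, the replicate number as a block, the 50 most abundant genes left out, only the compared stages in the fit, an estimated correlation and each library left out. After the data were seen, the spermatogonia libraries were summed, the 13 mitochondrial-genome genes or the marker genes of other cell types were left out, and each library was left out of the shares.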

Results

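RNA was sequenced from pig testis cells at 3 stages of sperm formation. Spermatogonia are the mitotic cells that found the germ line of the testis, spermatocytes are the cells in meiosis, and round spermatids are the haploid cells that meiosis leaves. There were 9 libraries, 3 for each stage. Spermatogonia and round spermatid libraries carried the numbers 1, 2 and 3, and spermatocyte libraries the numbers 2, 3 and 4. Library totals ran from 47963279 to 64639201 estimated counts over 22342 genes, of which 16802 passed the filter on low counts. The series set out to follow gene expression beside chromatin structure through these stages, and the comparisons ask which genes differ between each pair of them. Levels are counts scaled to the library total times its TMM factor (CPM), given as mean ± SD of n = 3 libraries. These factors ran from 0.774 for spermatocytes 3 to 1.26 for round spermatids 2. Log2 fold changes are given with ± standard error where it is named.

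Stage markers were spread unevenly over the labels. UCHL1, a deubiquitinating enzyme used as a marker of spermatogonia, stood at 26.1 ± 1.36 CPM in libraries labelled spermatogonia, 1.72 ± 0.679 in spermatocytes and 1.90 ± 0.686 in round spermatids. SYCP1, the transverse filament of the synaptonemal complex, stood at 29.3 ± 0.590, 166 ± 58.0 and 47.5 ± 19.8 CPM. PRM1, the protamine that packs sperm DNA, stood at 746 ± 9.67, 518 ± 275 and 3086 ± 708 CPM, abundant under every label. ACTA2, the smooth muscle actin of peritubular myoid cells, stood at 3.24 ± 0.205, 0.446 ± 0.526 and 1089 ± 185 CPM, and CYP17A1, a steroid-making enzyme of Leydig cells, at 98.0 ± 2.14, 0.662 ± 0.276 and 1.62 ± 0.436. The spermatogonia columns were headed with the name of the KIT receptor, whose own transcript stood at 6.36 ± 0.165 CPM there, 7.47 ± 0.747 in spermatocytes and 24.6 ± 1.54 in round spermatids. Stage names below mean the libraries so labelled.

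**Figure D1:**
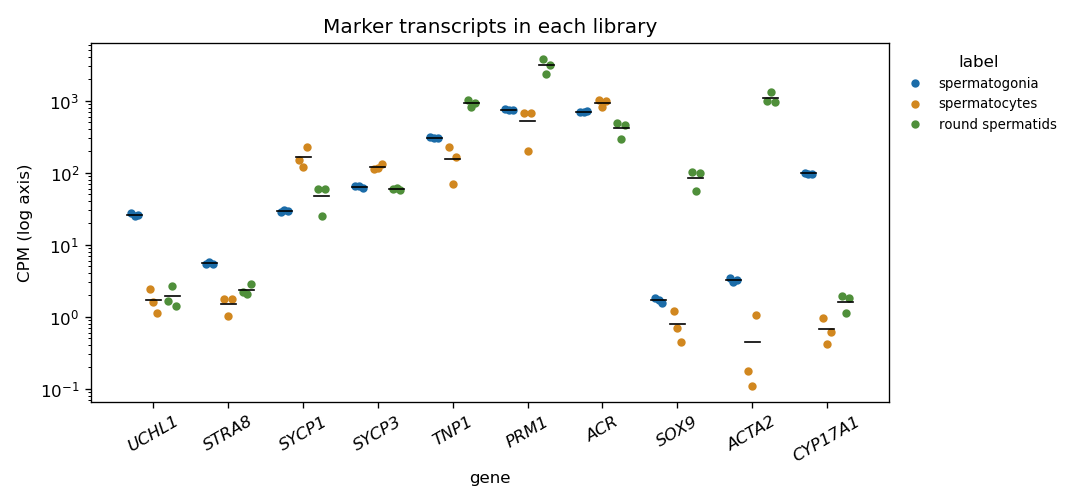
Level of 10 marker genes in CPM on a log axis. Each point is a library, coloured by its label, and each black line is the mean of 3 libraries. UCHL1 was highest in spermatogonia (26.1 CPM), SYCP1 in spermatocytes (166 CPM) and ACTA2 in round spermatids (1089 CPM).

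Libraries of a stage resembled each other, to different degrees. Pearson correlations of log2 CPM, taken across genes, which are not independent replicates, were 0.997 between spermatogonia libraries, 0.982 to 0.989 between spermatocytes and 0.979 to 0.993 between round spermatids. Between stages they were 0.907 to 0.919 for spermatocytes and spermatogonia, 0.737 to 0.786 for round spermatids and spermatocytes, and 0.768 to 0.796 for round spermatids and spermatogonia. The median chi-square per gene between pairs of spermatogonia libraries was 0.802 to 0.863, where counting alone gives 0.455. It was 5.12 to 10.8 for spermatocytes, 2.28 for round spermatids 1 and 3, and 20.9 to 22.6 for round spermatids replicate 2 against the others. The spermatogonia libraries were far closer than other replicates. They were kept as 3 samples because the labels list them so, and the values cannot tell separate samples from repeat preparations of 1 sample.

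Genes of the meiotic chromosome machinery were mixed between spermatocytes and spermatogonia: of 36 for recombination and the synaptonemal complex 18 were higher in spermatocytes and 10 lower, a shift not called with an estimated correlation (camera, adjusted p = 0.494). SYCP2, a lateral element of the synaptonemal complex, was 8.57-fold higher (983 ± 157 against 115 ± 3.19 CPM). HORMAD1, which marks unsynapsed chromosome axes, was 7.05-fold higher (309 ± 49.6 against 43.8 ± 1.59 CPM), and SMC6, of the SMC5/6 complex of chromosome repair, was 21.1-fold higher (1669 ± 282 against 79.2 ± 1.61 CPM). UCHL1 was 15.2-fold lower, and the Leydig cell hormone INSL3 was 304-fold lower (0.562 ± 0.169 against 173 ± 6.17 CPM). In edgeR's quasi-likelihood test, 4930 genes were higher and 7400 lower in spermatocytes at a Benjamini-Hochberg adjusted p below 0.05. The count of higher genes was 3229 with the closely similar spermatogonia libraries summed, 2433 on TPM and 2045 with TREAT, and that of lower genes 5913, 7434 and 3611.

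The largest rises past the fixed rule were those of RAB8B (log2 fold change 4.66 ± 0.503 SE), SMC6 (4.40 ± 0.421), ETFRF1 (4.14 ± 0.435), the homeobox gene LHX2 (3.87 ± 0.447) and CCDC112 (3.70 ± 0.298), with edgeR adjusted p from 2.95e-06 to 2.73e-05. The largest falls were those of INSL3 (-8.25 ± 0.219), SULT1C3 (-7.42 ± 0.265), CYP17A1 (-7.19 ± 0.300), the protease inhibitor A2M (-6.33 ± 0.377) and ACSF2 (-6.01 ± 0.183), with adjusted p from 3.37e-08 to 7.49e-07. Without spermatocytes replicate 4 the fall of A2M was -7.09. On Sscrofa11.1, matched by symbol, SMC6 lies on chromosome 3 from 120097361 to 120170974, RAB8B on chromosome 1 from 108772851 to 108840222, INSL3 on chromosome 2 from 59929591 to 59931220 and CYP17A1 on chromosome 14 from 113805616 to 113820445. Their Ensembl identifiers are ENSSSCG00000008614, ENSSSCG00000026571, ENSSSCG00000013887 and ENSSSCG00000010591.

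Of 36 measured genes of meiotic recombination and the synaptonemal complex, 18 rose, 10 fell and 8 did not pass, with 18 and 10 adjusted over the list alone. The list shifted upward against other genes (camera, adjusted p = 0.0182, and adjusted p = 0.494 with an estimated correlation). Its median was 0.44, and 0.02 with no normalization factors, where the median of all genes also fell, from -0.32 to -0.74. C14orf39, of the central element, rose by 3.63 on the log2 scale, SYCP1 by 2.50 and SYCP3 by 0.92. SPO11, which makes the breaks that start recombination, fell by 1.41 and MEI1, needed for those breaks, fell by 1.93. The recombinase gene DMC1 stood at 25.7 ± 10.4 against 39.1 ± 1.21 CPM (edgeR, adjusted p = 0.0383). Of 30 genes for cohesin, condensin and CTCF, 18 rose, 3 fell and 9 did not pass, with 18 and 3 adjusted over the list alone (camera, adjusted p = 0.00142, and adjusted p = 0.494 with an estimated correlation). The cohesin regulator PDS5B rose by 2.49, the condensin subunit NCAPG by 2.44 and the insulator protein gene CTCF by 1.29, while the meiotic cohesin gene REC8 fell by 2.43. STAG3, another meiotic cohesin gene, stood at 811 ± 57.0 against 931 ± 23.4 CPM and CTCFL at 2.83 ± 1.21 against 2.53 ± 0.198, neither past the test. In the piRNA pathway, which silences transposons in germ cells, 12 of 21 genes rose, 3 fell and 6 did not pass, with 12 and 3 adjusted over the list alone (camera, adjusted p = 0.0170, and adjusted p = 0.617 with an estimated correlation). MYBL1, a transcription factor of pachytene piRNA loci, rose by 2.60, ASZ1 by 1.68 and the helicase gene DDX4 by 1.43, while PLD6 fell by 1.11. The piRNA call was lost with no normalization factors (camera, adjusted p = 0.0630) and on TPM (adjusted p = 0.108). Beside these rises, 14 of 17 Leydig cell markers and 19 of 25 Sertoli cell markers fell. The spermatogonia libraries also held late germ cell transcripts, with 37 of 42 acrosome genes at a mean of 10 CPM or more. Falls such as those of SPO11, MEI1 and REC8 may depend on what those libraries held, which was not tested.

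Several groups were mostly lower in spermatocytes. Of 42 cytosolic ribosomal protein genes 33 fell, 5 rose and 4 did not pass, with 33 and 5 adjusted over the list alone (camera, adjusted p = 0.00142, and adjusted p = 0.617 with an estimated correlation). RPS9 stood at 43.0 ± 6.43 against 195 ± 3.71 CPM and RPS15 at 42.2 ± 6.78 against 191 ± 2.66, while RPS24 was higher, at 854 ± 159 against 237 ± 6.03. Of 20 genes of germline glycolysis 16 fell, 3 rose and 1 did not pass, with 16 and 3 adjusted over the list alone (camera, adjusted p = 0.0250, and adjusted p = 0.494 with an estimated correlation). GAPDH fell by 2.82, the hexose transporter gene SLC2A8 fell by 2.44 and the sperm enzyme gene GAPDHS fell by 2.34, while LDHA rose by 1.08. Markers of other cells fell with them. Of 17 Leydig cell markers 14 fell and 2 rose, with 14 and 2 adjusted over the list alone (camera, adjusted p = 0.00215, and adjusted p = 0.214 with an estimated correlation). CYP11A1, which starts steroid synthesis, stood at 0.153 ± 0.0227 against 25.5 ± 1.06 CPM. Of 25 Sertoli cell markers 19 fell and 1, the tight junction gene TJP1, rose, with 19 and 1 adjusted over the list alone (camera, adjusted p = 0.0284, and adjusted p = 0.494 with an estimated correlation). The inhibin subunit gene INHA stood at 0.0791 ± 0.0307 against 6.94 ± 0.331 CPM, CLDN11 at 0.135 ± 0.0792 against 8.19 ± 0.826 and SOX9 at 0.778 ± 0.384 against 1.68 ± 0.120. The Sertoli call held in 16 of 21 alternatives (camera, adjusted p from 0.00486 to 0.494); beside the estimated correlation (0.494), it was lost without spermatocytes replicate 3 (0.0573), with a filter on CPM of at least 1 in 3 libraries (0.0895), on TPM (0.154) and with no normalization factors (0.0634). The SOX9 call held in 18 of 22 (edgeR, adjusted p from 0.00119 to 0.116) and was lost without spermatocytes replicate 4 (0.0570), with limma-voom (0.0545), with the replicate number as a block (0.116) and with spermatogonia libraries summed (0.0630). Of 17 immediate early and stress genes 14 fell and 2 rose, with 15 and 2 adjusted over the list alone (camera, adjusted p = 0.0276, and adjusted p = 0.494 with an estimated correlation), and FOS fell by 2.68. With no normalization factors the immediate early genes lost their call (camera, adjusted p = 0.0630), and the call held in 19 of 21 alternatives, the estimated correlation counted.

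The remaining lists did not pass camera between spermatocytes and spermatogonia. Of 21 genes of undifferentiated spermatogonia 12 fell and 4 rose, with 12 and 5 adjusted over the list alone. The GDNF receptor gene RET fell by 3.11 and FGFR3 fell by 3.10, while the cadherin gene CDH1 rose by 1.91. ZBTB16, a transcription factor of spermatogonial stem cells, was lower at 1.60 ± 0.139 against 3.74 ± 0.350 CPM, and so was DMRT1 at 28.2 ± 4.40 against 52.0 ± 1.2. STRA8, the retinoic acid target of cells entering meiosis, was lower at 1.5 ± 0.432 against 5.51 ± 0.217 CPM, while KIT did not pass (edgeR, adjusted p = 0.104). Of 15 genes of differentiating spermatogonia 7 fell and 4 rose, and of 32 DNA replication genes 20 fell and 5 rose, with 7 and 4, and 20 and 6, adjusted over the list alone. Of 19 genes of the meiotic divisions 9 rose and 5 fell, as many as adjusted over the list alone, and the kinetochore motor gene CENPE rose by 3.11. Of 42 acrosome genes 25 fell and 12 rose, as many as adjusted over the list alone. In the spermatogonia libraries 37 of the 42 stood at a mean of 10 CPM or more. SPACA4, a protein of the sperm surface, stood at 5.16 ± 2.19 against 101 ± 1.2 CPM and SPACA3 at 2.13 ± 0.727 against 34.1 ± 0.561, while ZPBP2 was higher at 2026 ± 143 against 553 ± 6.97. ACRV1 fell by 1.59, SPACA1 fell by 1.10 and the transition protein gene TNP1 fell by 0.99. TNP2, PRM1 and PRM2 did not pass, with 288 ± 160, 518 ± 275 and 108 ± 52.6 CPM against 309 ± 10.3, 746 ± 9.67 and 184 ± 3.34. PGK1, an X-linked glycolytic gene, stood at 2.50 ± 0.769 against 8.41 ± 0.354 CPM, and the leukocyte gene PTPRC at 0.629 ± 0.406 against 0.469 ± 0.175 did not pass.

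Of 19 spermatid transcription regulators 10 fell and 5 rose, of 21 genes of histone replacement 10 fell and 6 rose, and of 20 nuclear lamina genes 11 fell and 6 rose. Adjusted over the list alone these were 10 and 5, 11 and 6, and 12 and 6. Of 47 nuclear genes of oxidative phosphorylation 31 fell and 7 rose, of 62 axoneme genes 23 fell and 21 rose, and of 20 sperm ion channel genes 7 fell and 10 rose, with the same counts adjusted over the list alone. For the axoneme genes the median was -0.06 and the mean -0.09 while camera's direction was upward, and for the ion channel genes the median was 0.22, the mean -0.15 and the direction upward. Of 35 DNA and histone methylation genes 15 rose and 8 fell, with 14 and 8 adjusted over the list alone. Of 7 X-linked parents of retrogenes 3 fell and 1 rose, and of 4 autosomal retrogenes 2 rose and 2 fell, with the same counts adjusted over the list alone. Of 20 myoid markers 14 fell and 1 rose, of 12 endothelial markers 7 fell and 1 rose, and of 19 leukocyte markers 7 fell and 2 rose, with the same counts adjusted over the list alone. Of 3 erythrocyte markers 1 rose and 1 fell, with 2 and 1 adjusted over the list alone. Medians of the meiotic division, axoneme, ion channel, methylation, X-linked parent and retrogene lists changed sign with the scaling.

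The median log2 change of all genes was -0.32 in this comparison, -0.14 with RLE size factors, -0.74 without normalization factors and -0.09 without the 50 most abundant genes, so list medians are read against it. Higher genes made up 39.98% of calls, against 26.83% without normalization factors, 24.66% on TPM, 46.36% with RLE size factors, 47.69% without a filter, 48.36% without mitochondrial-genome genes and 48.47% without the 50 most abundant genes. The excess of lower genes thus nearly vanished under some scalings. Calls of DMC1, CCNA1, ACR and LDHC lay near the threshold: edgeR adjusted p rose up to 0.131, 0.134, 0.137 and 0.138 with single libraries left out. They held in 11, 8, 11 and 12 of 23 alternatives, with adjusted p up to 0.188, 0.994, 0.995 and 0.753. Each of the 4 calls was lost when a spermatogonia library, whichever it was, was left out. They were also lost without spermatocytes 2 or 3 for DMC1, a spermatocyte library, whichever it was, or round spermatids 1 for CCNA1, spermatocytes 2 or 4 or round spermatids 3 for ACR, and spermatocytes 2 or 3 or round spermatids 3 for LDHC. Calls were gained without spermatocytes replicate 3 by KIT, PRM2 and STAG3 (edgeR, adjusted p = 0.0334, 0.0296 and 0.0460), without spermatocytes replicate 4 by PRM2 (0.0256) and without round spermatids replicate 2 by STAG3 (0.0241) and the oxidative phosphorylation list (camera, adjusted p = 0.0425). KIT, PRM2 and STAG3 passed in 7 of 23 alternatives each (adjusted p from 0.00112 to 0.562, 0.00399 to 0.194 and 0.000223 to 0.979), PRM1 in 2 of 22 (0.0160 to 0.509), and the list in 1 of 22 (0.0425 to 0.763, the highest with an estimated correlation). The meiotic division list passed in 1 of 22, with no filter (0.0439). SYCP3 lost its call on TPM (0.123), and TNP1 with spermatogonia libraries summed (0.0924) or with only the compared stages fitted (0.0923). The cyclin gene CCNA1 (183 ± 6.11 against 213 ± 2.25 CPM), the acrosin gene ACR (939 ± 106 against 704 ± 8.94) and LDHC (449 ± 73.2 against 349 ± 9.01) also changed sign with the scaling, the filter or the unit.

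Round spermatids held far less transcript of meiotic chromosome genes than spermatocytes, and more of protamines. SYCP2 was 17.9-fold lower (55.0 ± 14.2 against 983 ± 157 CPM), MEIOC, which holds cells in meiotic prophase, was 16.4-fold lower (51.9 ± 4.54 against 850 ± 113), and TDRD6, a tudor protein of germ granules, was 32.6-fold lower (17.2 ± 2.09 against 559 ± 123). PRM2 was 8.37-fold higher (902 ± 147 against 108 ± 52.6 CPM) and PRM1 5.96-fold higher. ACTA2 of smooth muscle was 2374-fold higher in the same libraries, and 7404-fold without spermatocytes replicate 4, which held most of its few spermatocyte counts. In edgeR's quasi-likelihood test 7177 genes were higher and 6124 lower in round spermatids at an adjusted p below 0.05.

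The largest rises were genes of the extracellular matrix and smooth muscle: MFAP4 (log2 fold change 12.32 ± 0.520 SE), KCNMB1 (11.60 ± 0.463), BGN (11.56 ± 0.675), COL3A1 (11.38 ± 0.661) and COL1A2 (11.35 ± 0.394), with edgeR adjusted p from 3.71e-09 to 8.54e-08. These fitted values rest on few counts in spermatocytes, where KCNMB1 had 7 counts in all 3 libraries together and COL1A2 had 18. Without spermatocytes replicate 4 the 5 rises were 13.77, 12.70, 13.46, 13.36 and 12.53, and that of COL3A1 was 10.79 without spermatocytes replicate 2. The largest falls were those of TDRD6 (-5.03 ± 0.182), the dynein gene DYNC2H1 (-4.50 ± 0.383), CKAP2L (-4.43 ± 0.158), MATCAP2 (-4.30 ± 0.174) and ANKFN1 (-4.23 ± 0.285), with adjusted p from 4.40e-09 to 1.33e-06. On Sscrofa11.1, matched by symbol, MFAP4 lies on chromosome 12 from 60141488 to 60144214 and TDRD6 on chromosome 7 from 41468589 to 41485146.

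Of the 36 recombination and synaptonemal complex genes 32 fell, 2 rose and 2 did not pass, with 32 and 2 adjusted over the list alone (camera, adjusted p = 7.26e-08, and adjusted p = 0.0377 with an estimated correlation). HORMAD1 fell by 4.0, SYCP1 fell by 1.80, SYCP3 fell by 1.03 and DMC1 fell by 1.49, while MSH4, which acts in crossing over, rose by 1.98. Of 19 genes of the meiotic divisions 15 fell and 4 did not pass, with 15 adjusted over the list alone (camera, adjusted p = 2.08e-05, and adjusted p = 0.0443 with an estimated correlation). The checkpoint kinase gene BUB1B fell by 3.81 and CENPE fell by 3.33. In the piRNA pathway 20 of 21 genes fell and 1 did not pass, with 20 adjusted over the list alone (camera, adjusted p = 3.45e-08, and adjusted p = 0.167 with an estimated correlation). TDRD1 stood at 20.6 ± 3.56 against 317 ± 86.7 CPM and TDRD12 at 2.49 ± 0.280 against 36.8 ± 4.36. Of 30 genes for cohesin, condensin and CTCF 22 fell, 5 rose and 3 did not pass, with 22 and 5 adjusted over the list alone (camera, adjusted p = 0.00100, and adjusted p = 0.288 with an estimated correlation). SMC6 fell by 3.21, the meiotic cohesin gene SMC1B fell by 2.79 and STAG3 fell by 1.57, while the X-linked genes HDAC8 and STAG2 rose by 2.95 and 1.94 and REC8 by 1.55. CTCFL rose by 1.44. CTCF stood at 58.1 ± 10.7 against 77.3 ± 7.34 CPM, a call lost without spermatocytes replicate 2 or 3 (edgeR, adjusted p = 0.0502 and 0.0590) and turned in sign without normalization factors; it held in 17 of 23 alternatives, with adjusted p up to 0.776. Beside these falls, 20 of 20 myoid markers and 23 of 25 Sertoli cell markers rose.

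Genes of the sperm tail were lower and protamine genes higher in round spermatids, in libraries where 20 of 20 myoid and 23 of 25 Sertoli cell markers were higher. Of 62 axoneme genes 47 fell, 7 rose and 8 did not pass, with 47 and 7 adjusted over the list alone (camera, adjusted p = 1.37e-07, and adjusted p = 0.0351 with an estimated correlation). The dynein heavy chain genes DNAH10 and DNAH2 stood at 35.4 ± 5.19 against 446 ± 125 and 34.8 ± 6.58 against 423 ± 101 CPM, while OAZ3, an antizyme of spermatids, was higher at 653 ± 72.9 against 125 ± 65.7. Of 20 sperm ion channel genes 13 fell and 2 rose, with 13 and 2 adjusted over the list alone (camera, adjusted p = 0.00127, and adjusted p = 0.0494 with an estimated correlation), and CATSPERE fell by 3.42. Of 21 genes of histone replacement 11 fell and 10 rose, as many as adjusted over the list alone (camera, adjusted p = 0.496). TNP1 rose by 2.59, TNP2 by 1.87 and the kinase gene TSSK6 by 2.70, while the acetyltransferase gene KAT5 fell by 2.17 and the ubiquitin ligase gene RNF8 fell by 2.06. Of 42 acrosome genes 18 fell and 11 rose, as many as adjusted over the list alone (camera, adjusted p = 0.141). ACR fell by 1.18 and LDHC fell by 1.80. ACRV1 and SPACA1 did not pass, at 52.7 ± 16.3 against 39.5 ± 20.1 and 40.8 ± 1.76 against 38.3 ± 13.7 CPM, and ACRV1 passed without spermatocytes replicate 4 (edgeR, adjusted p = 0.0493) but in none of the other 22 alternatives (up to 0.809).

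Of 42 ribosomal protein genes 41 rose and 1 did not pass, with 42 adjusted over the list alone (camera, adjusted p = 7.26e-08, and adjusted p = 0.288 with an estimated correlation). RPL4 stood at 565 ± 66.2 against 74.0 ± 10.2 CPM, RPS23 at 51.2 ± 23.5 against 7.29 ± 0.845 and RPL23 at 581 ± 154 against 99.3 ± 21.5. They rose in libraries where markers of other testis cells rose too. Of 20 myoid markers all 20 rose, as adjusted over the list alone (camera, adjusted p = 1.60e-08, and adjusted p = 0.0712 with an estimated correlation). Of 25 Sertoli cell markers 23 rose and TJP1 fell, with 23 and 1 adjusted over the list alone (camera, adjusted p = 3.96e-06, and adjusted p = 0.0494 with an estimated correlation). The activin subunit gene INHBA stood at 511 ± 131 against 1.15 ± 0.431 CPM, the growth factor gene GDNF at 75.1 ± 1.87 against 0.282 ± 0.0770 and SOX9 at 85.0 ± 26.1 against 0.778 ± 0.384. Of 12 endothelial markers 11 rose, as adjusted over the list alone (camera, adjusted p = 0.000725, and adjusted p = 0.288 with an estimated correlation), ENG by 6.09 and EGFL7 by 6.53. Of 19 leukocyte markers 18 rose, as adjusted over the list alone (camera, adjusted p = 0.000332, and adjusted p = 0.288 with an estimated correlation), TYROBP by 7.29 and PTPRC by 1.81. Of 17 immediate early and stress genes 16 rose and the chaperone gene DNAJB1 fell, with 16 and 1 adjusted over the list alone (camera, adjusted p = 1.53e-06, and adjusted p = 0.0713 with an estimated correlation). EGR1 stood at 3272 ± 1139 against 11.9 ± 9.62 CPM, JUNB at 653 ± 12.2 against 2.37 ± 1.34, and GADD45B rose by 8.41. With no normalization factors the call of DNAJB1 was lost (-0.45, edgeR adjusted p = 0.102), the 1 loss in 22 alternatives. Single spermatocyte libraries moved some of these folds by over 1.5 times: without replicate 4 the rises were 6.97 for ENG, 7.34 for EGFL7, 9.18 for GADD45B, 2.46 for PTPRC and 9.0 for EGR1 (8.10 with all libraries), and without replicate 2 that of TYROBP was 8.06. Of 17 Leydig cell markers 10 rose, among them CYP17A1 by 1.28, and 2 fell, as adjusted over the list alone (camera, adjusted p = 0.0511).

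Of 7 X-linked parents of autosomal retrogenes all 7 rose, as adjusted over the list alone (camera, adjusted p = 0.0115, and adjusted p = 0.383 with an estimated correlation). RPL10 stood at 210 ± 59.8 against 5.85 ± 1.30 CPM, PGK1 at 30.1 ± 8.63 against 2.50 ± 0.769 and RBMX at 199 ± 23.8 against 24.6 ± 6.44. All 4 measured autosomal retrogenes fell, as adjusted over the list alone (camera, adjusted p = 0.0141, and adjusted p = 0.114 with an estimated correlation), among them CSTF2T, which fell by 2.19, RPL10L, which fell by 1.33, and CETN1, which fell by 1.11. On TPM the retrogene call was lost (camera, adjusted p = 0.0502). The other lists did not pass camera. Of 21 genes of undifferentiated spermatogonia 9 rose and 6 fell, with 8 and 6 adjusted over the list alone. ZBTB16 rose by 1.44, DMRT1 by 0.59 and KIT by 1.72, and UCHL1 did not pass. On TPM the call of DMRT1 was lost (limma, adjusted p = 0.0852), the 1 loss in 23 alternatives. Of 15 genes of differentiating spermatogonia 9 rose and 4 fell, as many as adjusted over the list alone. STRA8 and SPO11 stood at 2.37 ± 0.383 against 1.5 ± 0.432 and 4.32 ± 0.992 against 2.62 ± 0.903 CPM, and their calls were lost without spermatocytes 3 or round spermatids 3 for STRA8 and without spermatocytes 2 or 3 or round spermatids 1 or 3 for SPO11 (edgeR, adjusted p up to 0.0911 and 0.0795). Over 23 alternatives they held in 15 and 14, with adjusted p up to 0.0936 and 0.0795. Of 32 DNA replication genes 15 fell and 8 rose, with 14 and 8 adjusted over the list alone. Of 19 spermatid transcription regulators 10 fell and 7 rose, and of 20 germline glycolysis genes 11 rose and 8 fell, as many as adjusted over the list alone. CCNA1 fell by 0.48, a fall absent with no normalization factors (-0.01, edgeR adjusted p = 0.922) and called in the other 22 alternatives.

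Of 47 nuclear genes of oxidative phosphorylation 22 fell and 11 rose, as many as adjusted over the list alone (camera, adjusted p = 0.108), and the list passed in 3 of 22 alternatives (0.0191 to 0.733, the highest with an estimated correlation), which were without spermatocytes replicate 4 (0.0191), with no filter (0.0460) and with the replicate block (0.0250). The DNA replication list passed in 1 of 22, with no filter (0.0484). Of 20 nuclear lamina genes 10 fell and 7 rose, as many as adjusted over the list alone, where the lamin gene LMNA rose by 6.75 and the lamin B receptor gene LBR fell by 3.41. Of 35 DNA and histone methylation genes 19 fell and 10 rose, as many as adjusted over the list alone (camera, adjusted p = 0.0522). The methylation and Leydig lists, both near the threshold, passed in 12 of 22 and 12 of 21 alternatives (camera, adjusted p from 0.0262 to 0.288 and 0.0252 to 0.167, the highest with an estimated correlation). With single libraries left out they went down to 0.0348 without spermatocytes replicate 2 and down to 0.0363 without round spermatids replicate 2. Of 3 erythrocyte markers 1 rose and 1 fell, with 0 and 1 adjusted over the list alone. Median, mean and camera's direction differed in sign for histone replacement (-0.37, 0.20, down), the acrosome (0.01, -0.25, down), the nuclear lamina (-0.28, 0.13, down) and erythrocyte markers (0.20, 0.53, down). Medians of these 4 lists and of the DNA replication and oxidative phosphorylation lists changed sign with the scaling. The median change of all genes was 0.19, with 0.08 under RLE size factors, 0.64 without normalization factors and -0.01 without the 50 most abundant genes. Higher genes made up 53.96% of calls, against 65.66% without normalization factors, 51.45% with RLE size factors, 48.07% on TPM, 49.48% without the 50 most abundant genes and 49.56% without mitochondrial-genome genes, so the balance turned with the scaling. The count of lower genes was 3220 with TREAT.

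**Figure D2:**
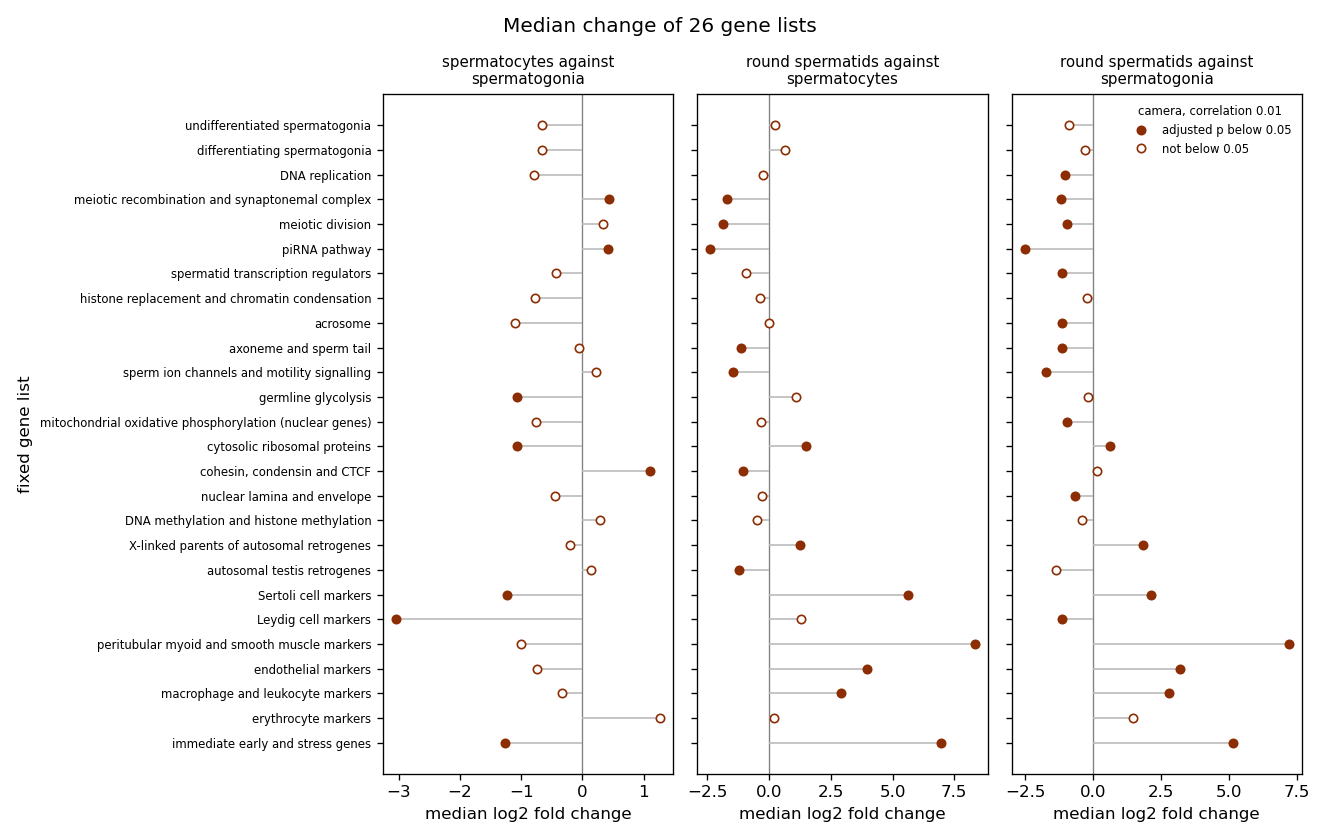
Median log2 fold change of the measured members of 26 gene lists in the 3 comparisons, each panel with its own horizontal axis. Filled points passed camera with the preset correlation at an adjusted p below 0.05, which 8, 14 and 18 lists did, and open points did not; with an estimated correlation 0, 5 and 1 lists passed.

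Round spermatids differed from spermatogonia in germ cell genes of several phases and in genes of other testis cells. Protamine and transition protein genes were higher: PRM1 by 4.14-fold (3086 ± 708 against 746 ± 9.67 CPM), PRM2 by 4.90-fold (902 ± 147 against 184 ± 3.34) and TNP1 by 3.03-fold (927 ± 105 against 306 ± 7.58). UCHL1 was 13.7-fold lower, and PIWIL2, which binds piRNAs, was 9.34-fold lower (4.40 ± 1.46 against 41.1 ± 0.972 CPM). COL1A1, a collagen of connective tissue, was 544-fold higher (4396 ± 1352 against 8.08 ± 0.302 CPM), while the Leydig cell genes INSL3 and CYP17A1 were 55.5-fold and 60.4-fold lower. In edgeR's quasi-likelihood test 6639 genes were higher and 6673 lower in round spermatids at an adjusted p below 0.05. On TPM 3652 were higher and 7714 lower, and with TREAT 4306 and 3446.

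The largest rises were those of OGN (log2 fold change 11.64 ± 0.631 SE, on 9 counts in all spermatogonia libraries together), KCNMB1 (11.45 ± 0.445), MFAP4 (11.16 ± 0.484), CD248 (10.39 ± 0.739) and NEXN (10.19 ± 0.605), genes of connective tissue, vessel walls and muscle, with edgeR adjusted p from 1.47e-08 to 4.85e-07. Without spermatogonia replicate 3 the rise of CD248 was 11.34. The largest falls were those of the opsin gene OPN4 (-8.05 ± 0.235), CYP17A1 (-5.92 ± 0.275), INSL3 (-5.79 ± 0.188), TDRD6 (-4.28 ± 0.176) and the phosphatase gene PTPN7 (-4.04 ± 0.228), with adjusted p from 3.84e-09 to 1.15e-07. On Sscrofa11.1, matched by symbol, OPN4 lies on chromosome 14 from 87645563 to 87660820 and COL1A1 on chromosome 12 from 26379087 to 26397180.

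Of the 36 recombination and synaptonemal complex genes 29 fell, 2 rose and 5 did not pass, with 29 and 2 adjusted over the list alone (camera, adjusted p = 2.00e-05, and adjusted p = 0.0539 with an estimated correlation). DMC1 fell by 2.09, SYCP3 did not pass at 58.8 ± 1.92 against 63.5 ± 2.28 CPM (on TPM it did, limma, adjusted p = 0.00870), and SYCP1 did not pass either but passed without round spermatids replicate 2 (edgeR, adjusted p = 0.00267) and in 7 of 23 alternatives in all (up to 0.939). SPO11 stood at 4.32 ± 0.992 against 6.97 ± 0.0903 CPM, a call lost without spermatogonia replicate 2 or 3 or round spermatids replicate 2 (edgeR, adjusted p = 0.0550, 0.0533 and 0.0672) and kept in 19 of 23 alternatives (up to 0.117). Of 19 genes of the meiotic divisions 13 fell and 6 did not pass, with 13 adjusted over the list alone (camera, adjusted p = 0.000736, and adjusted p = 0.0539 with an estimated correlation). The separase gene ESPL1 stood at 24.2 ± 5.85 against 344 ± 9.88 CPM and the kinase gene PKMYT1 at 30.2 ± 2.55 against 345 ± 6.18. In the piRNA pathway 20 of 21 genes fell, as adjusted over the list alone (camera, adjusted p = 1.08e-06, and adjusted p = 0.208 with an estimated correlation). Of 32 DNA replication genes 24 fell and 5 rose, as adjusted over the list alone (camera, adjusted p = 0.000736, and adjusted p = 0.208 with an estimated correlation). The polymerase gene POLE fell by 3.07 and the replicative helicase gene CDC45 fell by 2.74. Of 19 spermatid transcription regulators 13 fell and 3 rose, as adjusted over the list alone (camera, adjusted p = 0.00891, and adjusted p = 0.208 with an estimated correlation). CCNA1 fell by 0.70 and STAG3 fell by 1.77. Beside these falls, all 20 myoid markers and 21 of 25 Sertoli cell markers rose.

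Most genes of the acrosome and tail were lower in round spermatids than in spermatogonia, which the abundance of late germ cell transcripts in the spermatogonia libraries accompanied (PRM1 at 746 ± 9.67 CPM, ACR at 704 ± 8.94). In the same round spermatid libraries 20 of 20 myoid, 21 of 25 Sertoli, 11 of 12 endothelial and 15 of 19 leukocyte markers were higher. Of 42 acrosome genes 29 fell, 4 rose and 9 did not pass, with 29 and 4 adjusted over the list alone (camera, adjusted p = 0.000230, and adjusted p = 0.208 with an estimated correlation). SPACA4 stood at 8.73 ± 2.82 against 101 ± 1.2 CPM and the lysozyme-like gene LYZL4 at 2.71 ± 0.366 against 27.3 ± 0.409. The calyx genes CYLC2 and CYLC1 rose by 2.58 and 2.27, while ACRV1 fell by 1.18, SPACA1 fell by 1.0 and ACR fell by 0.77. With spermatogonia libraries summed the call of ACRV1 was lost (edgeR, adjusted p = 0.0590). Of 62 axoneme genes 49 fell, 3 rose and 10 did not pass, with 49 and 3 adjusted over the list alone (camera, adjusted p = 3.95e-07, and adjusted p = 0.0368 with an estimated correlation). CIMAP1A stood at 4.39 ± 1.03 against 48.5 ± 1.12 CPM and DNAH2 at 34.8 ± 6.58 against 326 ± 16.1. Of 20 sperm ion channel genes 16 fell and 2 rose, as adjusted over the list alone (camera, adjusted p = 0.000610, and adjusted p = 0.0539 with an estimated correlation), among them CATSPER3, which fell by 2.78, and the potassium channel gene KCNU1, which fell by 2.77. Of 47 nuclear genes of oxidative phosphorylation 33 fell and 7 rose, as adjusted over the list alone (camera, adjusted p = 0.000973, and adjusted p = 0.525 with an estimated correlation). NDUFS3 fell by 2.03 and COX8A fell by 2.21. Of 20 nuclear lamina genes 13 fell and 4 rose, as adjusted over the list alone (camera, adjusted p = 0.0478, and adjusted p = 0.195 with an estimated correlation), with SUN5 of the spermatid envelope at 4.12 ± 0.537 against 36.8 ± 0.882 CPM and LMNA at 764 ± 146 against 14.5 ± 0.380. TNP2 rose by 1.77, and of 21 genes of histone replacement 10 fell and 5 rose, as adjusted over the list alone (camera, adjusted p = 0.177).

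Of 42 ribosomal protein genes 24 rose, 5 fell and 13 did not pass, with 24 and 5 adjusted over the list alone (camera, adjusted p = 0.00891, and adjusted p = 0.531 with an estimated correlation). RPL37 rose by 2.59 and RPL23 by 2.52, while RPLP0 fell by 1.35. Of 7 X-linked parents of retrogenes 6 rose, as adjusted over the list alone (camera, adjusted p = 0.0117, and adjusted p = 0.355 with an estimated correlation), PGK1 by 1.84. Of 4 autosomal retrogenes 3 fell, as adjusted over the list alone (camera, adjusted p = 0.0934), among them RPL10L, which fell by 2.10, and GK2, which fell by 1.39. Both rises stood beside those of other cells' markers. Of 20 myoid markers all 20 rose, as adjusted over the list alone (camera, adjusted p = 4.31e-10, and adjusted p = 0.0539 with an estimated correlation), LUM by 10.17 and the myosin kinase gene MYLK by 8.98. Of 25 Sertoli cell markers 21 rose and 2 fell, as adjusted over the list alone (camera, adjusted p = 3.49e-05, and adjusted p = 0.0539 with an estimated correlation), INHBA by 7.64, GDNF by 6.92, KITLG by 6.55 and SOX9 by 5.66, while TJP1 fell by 0.43, not called with spermatogonia libraries summed (edgeR, adjusted p = 0.0642). Of 12 endothelial markers 11 rose, with 11 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.000610, and adjusted p = 0.252 with an estimated correlation), ROBO4 by 5.69 and CDH5 by 4.96. Of 19 leukocyte markers 15 rose, as adjusted over the list alone (camera, adjusted p = 0.000702, and adjusted p = 0.252 with an estimated correlation), PTPRC by 2.24. Of 17 immediate early genes 16 rose and 1 fell, as adjusted over the list alone (camera, adjusted p = 3.95e-07, and adjusted p = 0.0539 with an estimated correlation), EGR1 by 6.83 and JUNB by 6.23. Of 17 Leydig cell markers 12 fell and 4 rose, with 12 and 5 adjusted over the list alone (camera, adjusted p = 0.0478, and adjusted p = 0.195 with an estimated correlation).

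Of 21 genes of undifferentiated spermatogonia 12 fell and 7 rose, and of 15 genes of differentiating spermatogonia 6 fell and 5 rose, as many as adjusted over the list alone (camera, adjusted p = 0.373 and 0.763). STRA8 fell by 1.22 and KIT rose by 1.95, while ZBTB16 did not pass, at 4.32 ± 0.143 against 3.74 ± 0.350 CPM. DMRT1 stood at 42.4 ± 3.63 against 52.0 ± 1.2 CPM (edgeR, adjusted p = 0.0587), and passed without spermatocytes replicate 2 or 3 or round spermatids replicate 2 (adjusted p = 0.0425, 0.0198 and 0.0315), in 5 of 23 alternatives in all (0.00559 to 0.209). TEX101, a germ cell surface protein, stood at 13.1 ± 0.840 against 181 ± 6.25 CPM. Of 30 genes for cohesin, condensin and CTCF 12 rose and 11 fell, with 11 and 11 adjusted over the list alone (camera, adjusted p = 0.846). CTCF rose by 0.88 and CTCFL by 1.61, while REC8 fell by 0.88. On TPM the rise of CTCF was 0.24 and not called (limma, adjusted p = 0.142), the 1 loss in 23 alternatives. Of 20 germline glycolysis genes 9 fell and 7 rose, and of 35 DNA and histone methylation genes 18 fell and 10 rose, as many as adjusted over the list alone (camera, adjusted p = 0.516 and 0.159). LDHC fell by 1.44. Of 3 erythrocyte markers 2 rose and 1 fell, as adjusted over the list alone. Median, mean and camera's direction differed in sign for differentiating spermatogonia (-0.29, 0.27, down) and for cohesin, condensin and CTCF (0.15, 0.03, down). The ribosomal, lamina and Leydig calls held in 19 of 22, 11 of 22 and 14 of 21 alternatives. Their adjusted p was highest with an estimated correlation (camera, 0.531, 0.195 and 0.195), and 0.0686, 0.151 and 0.0966 on TPM. The ribosomal call was lost without round spermatids replicate 2 and the Leydig call too (0.0552 for each), and the lamina call without spermatocytes replicate 2, without spermatocytes replicate 4, without round spermatids replicate 1 or without round spermatids replicate 3 (adjusted p = 0.0504, 0.0531, 0.0517 and 0.0526). The Leydig call was also lost without spermatocytes replicate 4 (0.0571) or without round spermatids replicate 1 (0.0517). The lamina call was also lost with no normalization factors (0.0596), upper-quartile factors (0.0505), a filter on CPM of at least 1 in 3 libraries (0.0647), the replicate block (0.0511) and marker genes left out (0.0541), and the Leydig call with the replicate block (0.0679) and with only the compared stages fitted (0.0570). Higher genes made up 49.87% of calls, against 32.13% on TPM and 52.11% with RLE size factors.

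Genes on the X chromosome, which is silenced in male meiosis, moved apart from autosomal genes. The median log2 change of 415 X-linked genes lay -0.56 from that of 12252 autosomal genes in spermatocytes against spermatogonia, where 236 fell and 43 rose (camera, p = 0.000253, and p = 0.448 with an estimated correlation). In percent, 56.87 of X-linked genes fell and 10.36 rose, against 43.98 and 30.2 of autosomal genes. Chromosome 12 had the lowest autosomal median, -0.64, beside -0.86 for X. Between round spermatids and spermatocytes the X-linked median lay 1.92 above, and 336 rose and 11 fell (camera, p = 4.73e-14, and p = 0.145 with an estimated correlation). That was 80.96% higher and 2.65% lower, against 42.35% and 38.37% of autosomal genes. Between round spermatids and spermatogonia the X-linked median lay 1.40 above, and 277 rose and 47 fell (camera, p = 7.16e-09, and p = 0.247 with an estimated correlation). That was 66.75% higher and 11.33% lower, against 39.05% and 40.48% of autosomal genes. In the same round spermatid libraries 66 of 76 myoid, endothelial, leukocyte and Sertoli markers were higher than in both other stages. Whether the X-linked rises depend on RNA of such cells was not tested. X-linked genes took 0.504 ± 0.00223% of counts in spermatogonia, 0.238 ± 0.0834% in spermatocytes and 1.53 ± 0.118% in round spermatids, whose libraries also held the X-linked matrix gene BGN at 1426 ± 59.7 CPM. The 13 genes of the mitochondrial genome took 0.697 ± 0.00815%, 1.63 ± 0.379% and 7.49 ± 3.8%. Round spermatids replicate 2 held 3.14% there, against 9.09% and 10.2% in replicates 1 and 3. Each pair of stages differed in both shares with no overlap, at a two-sided p of 0.1 in the exact permutation test, the smallest that 3 against 3 allow. The differences in share between stages depended on the unit. Between round spermatids and spermatocytes the X-linked difference was 1.29 points and 0.856 on TPM, and the mitochondrial difference was 5.85 points, 19.2 on TPM and 0.217 without the 50 most abundant genes, of which 9 are mitochondrial.

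**Figure D3:**
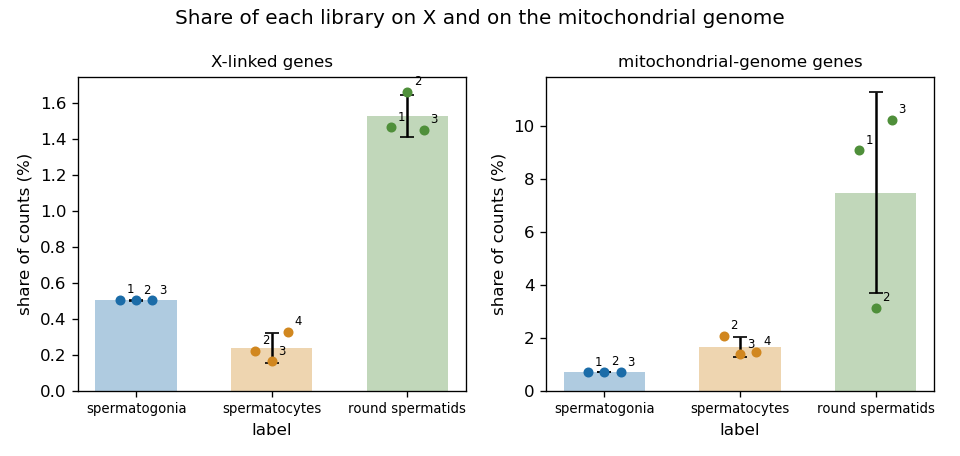
Share of each library's counts, in percent, on X-linked genes (left) and on the 13 mitochondrial-genome genes (right). Bars are means of 3 libraries, error bars are SD, points are libraries and digits their replicate numbers. X-linked genes took 0.238% in spermatocytes and 1.53% in round spermatids.

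Across the 3 stages together, 15735 of 16802 genes differed (edgeR F-test, adjusted p below 0.05). Enriched in a stage, by a log2 difference of at least 1 against both others, were 1852 genes in spermatogonia, 1556 in spermatocytes and 4022 in round spermatids. Those of spermatocytes numbered 805 without normalization factors and 784 on TPM, and those of round spermatids 2187 on TPM. Enriched here means high in libraries so labelled, not in a pure cell type. Of 76 myoid, endothelial, leukocyte and Sertoli markers, 66 were higher in round spermatids than in both other stages. The most abundant genes enriched in spermatogonia were TRIM28, a corepressor, at 2573 ± 9.83 CPM, the peroxidase gene GPX4, IZUMO4 of the acrosome list, RPLP0 and ATG9A. The most abundant of spermatocytes were DKKL1, a protein of the acrosome, at 12980 ± 3245 CPM, the RNA-binding protein gene YBX1 at 12045 ± 1407, PABPC1, HSP90AA1 and PSIP1 at 7907 ± 816. The most abundant of round spermatids were the mitochondrial-genome genes ATP6, CYTB, ND4, COX1 and COX3, with ATP6 at 17983 ± 11757 and COX1 at 7211 ± 1316 CPM. The calls against spermatocytes were lost for ATP6 without spermatocytes replicate 4 or round spermatids replicate 3 (edgeR, adjusted p = 0.0541 and 0.0540) and for DKKL1 without spermatocytes replicate 2 (adjusted p = 0.0526). With the replicate number as a block ATP6 (0.190) and CYTB (0.0779) lost them. The calls of ATP6, CYTB and DKKL1 held in 18 of 21, 20 of 21 and 21 of 22 alternatives. By fry, which does not compare a list with other genes, 24, 23 and 24 of the 26 lists moved one way on balance and 25, 25 and 26 in either direction, at an adjusted p below 0.05.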

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

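Summing the spermatogonia libraries, leaving out mitochondrial-genome or marker genes, and leaving single libraries out of the shares were chosen only after the results were seen. For genes higher in spermatocytes than spermatogonia the count moved from 4930 to 2433 on TPM, 2045 with TREAT and 3229 with spermatogonia libraries summed, and for lower genes from 7400 to 3611 with TREAT. For genes lower in round spermatids than spermatocytes TREAT gave 3220. For round spermatids against spermatogonia it gave 4306 higher and 3446 lower, and TPM gave 3652 higher. TREAT asks for a larger change by construction, and the cause was not tested for the others. Lists called in the 3 comparisons fell from 8, 14 and 18 to 0, 5 and 1 with an estimated correlation and to 5, 9 and 11 without marker genes, which removes 7 lists by construction, and without normalization factors the first was 5. The X-linked differences of -0.56, 1.92 and 1.40 lost their call with an estimated correlation (p = 0.448, 0.145 and 0.247). Genes enriched in spermatocytes numbered 805 without normalization factors and 784 on TPM, and genes enriched in round spermatids 2187 on TPM. The X share difference of round spermatids to spermatocytes was 1.29 points, 1.52 without the 50 most abundant genes and 0.856 on TPM, and to spermatogonia 1.02, 1.24 and 0.566. The mitochondrial share difference was 0.936, 0.0206 and 5.52 points for spermatocytes against spermatogonia, 5.85, 0.217 and 19.2 for round spermatids against spermatocytes, and 6.79, 0.238 and 24.7 against spermatogonia, where 9 of the 50 genes left out are mitochondrial. For spermatocytes against spermatogonia CCNA1 turned to 0.01 (0.0051) without a filter, 0.02 (0.0236) without the 50 genes and 0.02 (0.0200) without mitochondrial genes, ACR to -0.11 on TPM, and LDHC to -0.0629 without factors and -0.17 on TPM; CTCF turned to 0.0355 in round spermatids against spermatocytes without factors. The cause was not tested. Of 4978 alternatives of 219 gene results, 4846 kept their side of the threshold, 88 lost the call and 37 gained it. Another 7 turned in sign with a call in either fit. A sign change of a gene called in neither fit was counted among the 4846. Replicate numbers showed no pairing of the libraries. Deviations of same-numbered libraries correlated at 0.0283 or below, and those of other pairs from -0.0903 to 0.093. With 3 libraries per stage this cannot exclude shared animals. As a block the replicate numbers gave 4638 higher and 7277 lower, 7067 and 5949, and 6625 and 6753 genes, and moved no count by over 1.5 times. The block changed calls of 6 named genes, however. For spermatocytes against spermatogonia SOX9 (adjusted p = 0.116), CCNA1 (0.205) and ACR (0.105) lost theirs and PRM2 gained one (0.0385), and for round spermatids against spermatocytes ATP6 (0.190) and CYTB (0.0779) lost theirs (edgeR). With single libraries left out, the counts ranged from 4438 to 5241 and 6870 to 7692, from 6939 to 7434 and 5934 to 6332, and from 6204 to 6989 and 6264 to 6949. Depth limits genes under 1 CPM, and folds against a few counts, as for KCNMB1, are the least precise.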

Other observations

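The 7 tests of the 3 patterns below were chosen only after the results were seen; the counts over other splits of the samples were set before.

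Transcripts of other testis cells stood high in libraries labelled round spermatids, with COL1A1, the most abundant of 76 markers of the myoid, endothelial, leukocyte and Sertoli lists, at 4396 CPM and ACTA2 at 1089. Of these 76, 66 (86.8%) were higher there than in both other stages, which describes the pattern and tests no explanation of it; 12 and 7 reached 10 CPM in spermatogonia and spermatocytes, and 0 are held by another list. A lower share of germ cells beside the same mix of other cells as in spermatogonia libraries would raise Leydig and myoid markers alike. Against that, in round spermatids against spermatogonia the upper quartile of the Leydig list was 0.49 (0.494) on the log2 scale. The lower quartile of the myoid list was 5.41, and the medians of the Leydig and myoid lists were -1.13 and 7.21. Against spermatocytes 10 of 17 Leydig and 20 of 20 myoid markers were higher, with medians of 1.30 and 8.32. A lower share of germ cells beside another mix of other cells stays open. RNA from other testis cells and expression by the labelled cells both stay open, since no value here decides between them, and the labels name no sort or gate that would remove such cells.

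Transcripts of late germ cells stood high in libraries labelled spermatogonia. Carry-over from the round spermatid libraries is argued against by the myoid list, at a median of 0.676% of its round spermatid level (upper quartile 2.35%), where 145 genes of histone replacement, acrosome, axoneme and ion channels stood at a median of 221% (lower quartile 117%). An exchange of labels between spermatogonia and round spermatids stays open: 104 of the 145 were higher in libraries labelled spermatogonia and 14 in those labelled round spermatids, among them PRM1, PRM2, TNP1 and TNP2. Other lists ran with the labels, against them or both ways. In libraries labelled round spermatids 24 of 32 DNA replication genes were lower and 5 higher, against an exchange. Of 19 spermatid transcription regulators 13 were lower there and 3 higher, as an exchange would give. Of genes of undifferentiated spermatogonia 12 were lower and 7 higher, with UCHL1 lower and KIT higher. RNA from later germ cells and expression by spermatogonia themselves stay open too. The 37 of 42 acrosome genes at 10 CPM or more describe the pattern without telling them apart. A wrong match of columns to the spermatogonia titles stays open as well. The match rests on the meaning of the KIT heading, left another column with a shared number unused, and was not tested.

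Round spermatids replicate 2 held a low mitochondrial share, with a median log2 ratio of -1.62 over the 13 genes against replicates 1 and 3. Less RNA from other testis cells in it is argued against by the somatic lists, whose median log2 ratio was -0.15 (-0.147), with quartiles of -0.45 and 0.25. Mitochondrial transcripts as its one difference are argued against by the median chi-square per gene without them, 16.1 to 18.2 against the other replicates and 2.25 between those. No biological explanation was tested.

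Other splits of the samples were counted. For genes differing between any stages 1 of 100 splits, the real one, gave as many (15735, highest other 7581). For genes enriched in round spermatids 1 of 100 did (4022, highest other 3571). Both shares were under 0.05 for regrouping of these libraries. They cannot exclude chance between animals, since the labels name none and libraries of a stage may be repeat preparations. For genes enriched in a stage, each other split was given the largest enriched count among its 3 groups. For genes enriched in spermatogonia and in spermatocytes 5 of 100 splits gave as many (1852 and 1556, highest other 3571). The 4 other splits all kept the round spermatid libraries together, a structure of the samples. Their largest count can thus belong to a group unlike spermatogonia or spermatocytes, so this count neither excludes chance nor speaks for it. Splits that kept no stage together gave 0. Between pairs of stages the 10 splits are too few for a share under 0.05. The real counts were 4930 and 7400, 7177 and 6124, and 6639 and 6673 genes, with 0 in any other split, each 1 of 10. Lists called were 8, 14 and 18, with 8, 15 and 16 in the highest other split, and 4, 3 and 1 of 10 splits gave as many. The X-linked differences were -0.56, 1.92 and 1.40, with 0.38, 0.66 and 0.45 as the highest other, each 1 of 10.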
